A study of Mus musculus with 8 samples.

How the data were processed

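The samples were mouse embryonic stem cells of the 129/Ola strain differentiated on gelatin in serum-free N2B27 medium. Per the labels, cross-linked chromatin was sonicated to fragments of about 200 bp, 10 to 15 ng of precipitated or input DNA went into each Illumina library, fragments of 200 to 350 bp were selected, and 18 cycles of PCR followed. There were 4 ChIP libraries (H3ac on days 2, 4 and 6, HDAC1 on day 2) and 4 input libraries, 1 for each target and day, and groups and days were taken from the labels. The intervals cover counting error only, because PCR copies and neighbouring peaks are not independent.

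Reads were aligned with Bowtie 0.12.8 to mouse build mm10, per the submitters' processing notes. The deposited peak names begin with MACS, the name of a peak caller, and its version, cut-off and use of the input libraries are not given in the sources used here. Each deposited file listed the peaks of 1 ChIP library as chromosome, start, end, name and a score, with no header. The peak scores are the authors' values and run from 50 to at most 3100, where the highest values appear capped. The scale of the score is not stated, so it served only to rank or filter peaks within a list. Called peaks depend on depth, enrichment and the caller's settings, so a gene without a peak in 1 list can still be acetylated or bound, and fewer peaks in a list can mean fewer reads. Total read counts were not used here.

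Genes came from a RefSeq gene table of assembly GRCm38.p6, which has the coordinates of mm10, and 21887 protein-coding genes on chromosomes 1 to 19, X and Y were used. The table gives the start and end of each gene without strand, transcripts or exons. Promoters were therefore replaced by gene ends: a gene counted as marked when a peak lay within 1 kb of either end, and a peak location was a gene end, a gene body or outside protein-coding genes, with no split into exons, introns and UTRs. More than 90% of marked genes in each list had a peak at a single end. Peaks on other contigs or on the mitochondrial genome, 10 on day 2 and 1 in each of the other lists, were left out of location and placement. All coordinates are 1-based.

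Peak lists were compared by overlap of at least 1 bp. Each observed overlap was set beside 1000 placements of the same peak widths at random on the same chromosome, between the first and last annotated gene, and 100 such placements served for peak locations. Shares have 95% Wilson intervals. For gene lists the number of members with a gene-end peak was given as a percentile among 10000 random lists of the same size, counting ties at 50%. Numbers kept from day 2 to a later day were set against 10000 random lists matched on decile of day 2 score, drawn from all day 2 genes. Differences and matched shares for HDAC1-bound and X-linked genes were computed against day 2 genes outside the set, weighted by decile of score, so they and the percentiles use different pools. Lists were at first drawn from the genes outside the list alone. Simulated data showed that this placed too many null lists outside the range, and the draw was changed after the real values had been seen, which brought the day 6 difference at HDAC1-bound genes inside the range. Genes gained were set against random lists of genes without a day 2 peak. Percentiles describe these libraries, and no p-value was computed, since genes and peaks are not replicates.

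The groups, comparisons, tests, alternatives and the 21 gene lists were chosen before the data were examined. The lists were pluripotency, primed epiblast, neural progenitor, neuron, mesendoderm, Nodal and TGF-beta, BMP, Wnt, and FGF and ERK signalling, class I HDAC complexes, acetyltransferases and BET readers, Hox clusters, trophoblast, extraembryonic endoderm, neural crest, germ line, cell cycle, replication-dependent histones, and as controls cytosolic ribosomal proteins, olfactory receptors and adult tissue genes. Genes were named by a rule also chosen then. It covered 24 candidate genes whatever their values, up to 4 members per list and class by score (a peak on every day, on day 2 but not day 6, later but not on day 2, or of HDAC1), the 5 highest-scoring genes of each library, and the 5 highest-scoring genes with a peak on day 6 and none on day 2. Utf1, Gdf3 and Hoxa3 had also been looked at before the rule was applied. Any other gene named was chosen after its values were seen. The replacement of promoters by gene ends, the alternative of gene ends with no other gene end within 2 kb, and the count of peaks anywhere in a gene or within 10 kb were chosen after the data were examined, as was a list of 36 REST targets, which was written from general knowledge.

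The procedures were tested on simulated data. With 25% of simulated HDAC1 peaks placed on day 2 H3ac peaks and the rest at random, 25.5% of 5285 overlapped. For retention, a planted difference of 5 points among 8878 genes gave a mean matched difference of 4.96 points over 100 runs and lay outside the central range of random lists in 96% of runs. A planted difference of 2 points did so in 33% of runs and no difference in 6%, so the procedure misses many differences of that size. The simulation drew retention for each gene independently, whereas neighbouring genes can share a peak. The real spread without a difference may therefore be wider than the simulated runs and the matched lists show. Random lists lay outside the range in 4% of runs, and lists of 25 genes drawn at 2 times the rate in 41%.

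Alternatives were the higher-scoring 50% of each list, equal numbers of top-scoring peaks (5286 per list), windows of 2.5 and 0.5 kb, autosomal genes, overlap by 50% of the shorter peak or within 1 kb, placement within 10 kb of gene ends, matching on peak width or none, and merging of peaks within 1 kb. Alternatives that needed transcript starts or CpG content of promoters were not run. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.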

Results

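Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map acetylated histone H3 (H3ac), a mark of active promoters and enhancers, and the histone deacetylase HDAC1 in mouse embryonic stem cells during differentiation. Embryonic stem cells are pluripotent cells from the early embryo, here of the 129/Ola strain, and they were grown on gelatin in the serum-free medium N2B27, in which many cells take a neural fate. H3ac was mapped on days 2, 4 and 6, and HDAC1, carried as an epitope-tagged protein and precipitated with an antibody against the FLAG tag, was mapped on day 2. Each target and day had 1 ChIP library and 1 input library, which made 8 libraries in all and gave no replicates. Differences between days or targets therefore have no replicate check, the 95% intervals below (Wilson) cover counting error over peaks or genes only, and the peak lists give no read depth. The 4 deposited peak lists held 17368 H3ac peaks on day 2, 12945 on day 4 and 5553 on day 6, and 5286 HDAC1 peaks on day 2.

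The first comparison, among the 3 H3ac days, asked where H3 was acetylated and how the acetylated genes differed along the time course. Genes of protein synthesis carried H3ac on every day. All 76 cytosolic ribosomal protein genes had an H3ac peak within 1 kb of a gene end on day 2, 75 had one on day 4 and 70 on day 6, against 30.8, 28.9 and 17.7 in random lists of 76 protein-coding genes. The highest-scoring gene-end peaks of day 2 belonged to Rpl13a, a ribosomal protein gene, to Gapdh, a glycolytic enzyme gene whose peak also reached the end of Ncapd2, and to Brd2, a reader of acetylated histones that shared its peak with H2-DMa. Of 1106 olfactory receptor genes, a control expected to be silent in these cells, 3 had a gene-end peak on day 2 and 0 on days 4 and 6. Of 16 genes of adult tissues, the numbers were 1, 2 and 2.

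Across all 21887 protein-coding genes, 8878 (40.6%, interval 39.9 to 41.2%) had a gene-end H3ac peak on day 2, 8313 (38.0%, 37.3 to 38.6%) on day 4 and 5096 (23.3%, 22.7 to 23.8%) on day 6. A set of 4055 genes had one on all 3 days. Of the day 2 genes, 79.0% (78.1 to 79.8%) also had a gene-end peak on day 4 and 49.9% (48.8 to 50.9%) on day 6. The shared numbers were 7013 and 4429 genes, against 3372 and 2067 for independent lists of the same sizes. A further 1300 genes had a day 4 but no day 2 gene-end peak, and 667 genes had a day 6 but no day 2 peak. The highest-scoring genes of the latter group included Meis1, which encodes a partner of Hox transcription factors, and Fzd3, which encodes a Wnt receptor. They also included the Hox genes Hoxb2 and Hoxb3, which were marked by the same day 6 peak. Meis1, on chromosome 11 from 18880428 to 19019651 in build mm10, held the peak ranked 2 of day 4 and 24 of day 6. Scores are the authors' own, and they rank peaks within a list here. Scores and ranks from different lists cannot be read as a change between days.

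The lists differed in length and in peak width, and this bears on every comparison between days. The median H3ac peak was 591 bp wide on day 2, 792 bp on day 4 and 1898 bp on day 6, so that the day 6 list, with 5553 peaks against 17368, covered 11.6 Mb against 12.8 Mb. A day 6 peak lay within 1 kb of 38.2% of day 2 peaks (37.5 to 39.0%). Of day 2 H3ac peaks, 50.2% (49.5 to 51.0%) overlapped a day 4 peak by at least 1 bp and 35.0% (34.3 to 35.7%) a day 6 peak, against means of 0.864% and 0.637% when the peaks were placed at random. Overlap went with score. Day 4 peaks overlapped 18.8% of the lowest-scoring 10% of day 2 peaks and 96.3% of the highest-scoring 10%, and day 6 peaks overlapped 13.9% and 72.0%. When the 5286 highest-scoring peaks of each list were used, gene-end peaks marked 4873 genes on day 2, 4982 on day 4 and 4909 on day 6. Equal numbers of peaks bring these totals together by construction, and day 6 peaks remained wider. Here and below, lists of equal length therefore cannot tell a loss of acetylation from a technical difference between libraries.

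**Figure D1:**
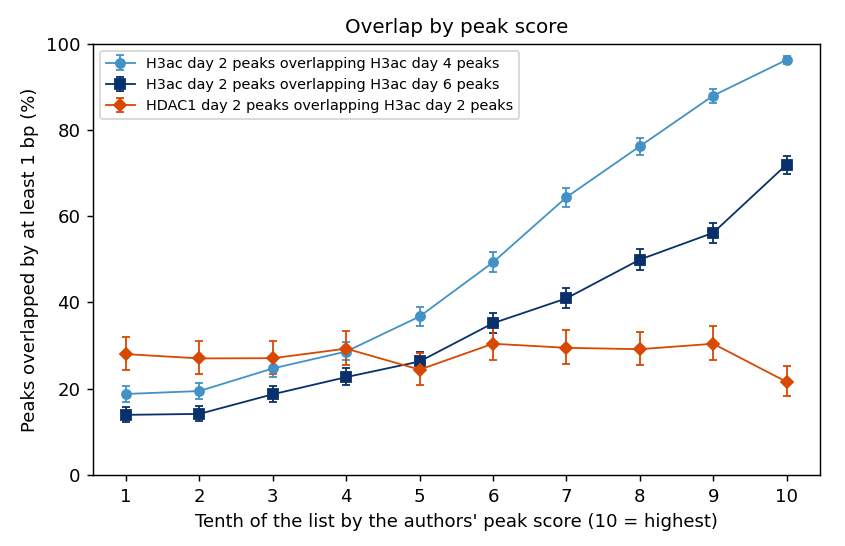
Share of peaks (%) overlapping a peak of a second list by at least 1 bp, in 10 equal parts of the first list ordered by the authors' score, with 95% Wilson intervals as bars. The share of day 2 H3ac peaks overlapped on day 4 runs from 18.8% in the lowest part to 96.3% in the highest, while the share of HDAC1 peaks overlapping day 2 H3ac peaks is 28.0% in the lowest part and 21.6% in the highest.

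H3ac peaks lay at gene ends far more often than random placements did. The midpoint lay within 1 kb of an end of a protein-coding gene for 52.4% (51.7 to 53.1%) of day 2 peaks, 60.0% (59.1 to 60.8%) of day 4 peaks and 67.1% (65.9 to 68.4%) of day 6 peaks, against 3.23%, 3.21% and 3.15% for random placements. Gene bodies held 32.8%, 30.1% and 27.0%, and regions outside protein-coding genes held 14.8%, 9.92% and 5.85%. Within 0.5 kb of a gene end the shares were 30.5%, 32.0% and 37.4%. With equal numbers of top-scoring peaks, the gene-end share was 74.5% on day 2 and 72.3% on day 4, above the 67.1% of the full day 6 list, so the order of the days turned with the length of the lists.

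The second comparison followed genes of pluripotency and of the lineages that embryonic stem cells can form. Of 25 pluripotency genes, 15 had a gene-end peak on day 2, 5 on day 4 and 6 on day 6, and with equal numbers of top-scoring peaks the numbers were 8, 5 and 5. The strongest on day 2 was Pou5f1, which encodes the pluripotency factor Oct4. Its day 2 peak had score 1035.01, rank 32 of 17368, and no gene-end peak was listed on days 4 or 6. Utf1 (score 607.20), Fgf4 (216.58) and Dppa4 (147.91) likewise had gene-end peaks on day 2 and none on days 4 and 6. Among 32 neural progenitor genes the numbers were 6, 14 and 6 (13.0, 12.2 and 7.45 in random lists, percentiles 0.5, 74.7 and 28.5). By the higher score of days 4 and 6, the genes with a day 4 but no day 2 peak were led by Zic1, Sox1, Fabp7 and Zfp521. The Fabp7 peak scored 53.67 on day 4, near the lowest score of 50, and 170.44 on day 6.

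Of the 15 pluripotency genes with a day 2 peak, 5 had one on day 4, where random lists matched on decile of day 2 score kept 11.6 on average and none of 10000 kept as few. On day 6, 5 of the 15 had a peak against 7.69 in matched lists (percentile 7.11). With equal numbers of top-scoring peaks, 3 of 8 were kept on day 4 against 6.62 in matched lists (percentile 0.135). The 4 members with a peak on every day were Sox2, Sall4, Lin28a and Tet2. Sox2, which serves pluripotent cells and neural progenitors alike, had a peak of score 302.68 on day 2, of 1122.54 (rank 21) on day 4 and of 1070.72 (rank 25) on day 6, the last being 10001 bp wide and spanning the whole gene, which lies on chromosome 3 from 34649995 to 34652461. Nanog (score 52.10) and Klf4 (52.61) had low-scoring day 2 gene-end peaks and none later, and Esrrb and Zfp42 had none on any day. Near misses bear on these calls: a Nanog day 4 peak (score 71.61) lay 1201 bp and a Zfp42 day 2 peak (score 62.31) 1005 bp from a gene end, and both enter with a window of 2.5 kb. Nanog also had a day 6 peak 3362 bp away, and Esrrb had internal peaks on days 2 and 4. Among 14 genes of the primed epiblast, the state that follows naive pluripotency, 12 had a gene-end peak on day 2, 9 on day 4 and 6 on day 6. Zic2, Sox4, Sox11 and Sall2 had one on every day, while Lef1, Pou3f1, Dnmt3b, Foxd3, Fgf5 and Otx2 had one on day 2 and none on day 6. Cdh2, which encodes N-cadherin, had peaks on day 4 (score 525.22) and day 6 (466.13) without one on day 2.

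Of the 26 neural progenitor genes with no day 2 gene-end peak, 11 had one on day 4, against 2.60 in random lists of genes without a day 2 peak (percentile 100), and 4 had one on day 6 against 1.33 (percentile 97.4). With equal numbers of top-scoring peaks the list gave 1, 5 and 6 members on days 2, 4 and 6, so the larger number on day 4 than on day 6 was not seen with lists of equal length. Sox1, an early neural marker on chromosome 8 from 12395519 to 12399555, carried 5 H3ac peaks in or within 10 kb of the gene on day 4, the strongest of score 181.29, and none on days 2 or 6. Zfp521 had gene-end peaks on day 4 (score 104.22) and day 6 (135.67). Nes, which encodes the intermediate filament nestin, had one on day 2 (72.95, below the median score of 80.21) and on day 4 (120.24, above the median of 101.61). Pax6 had no gene-end peak, and its internal peaks reached score 71.45 on day 2, 567.11 on day 4 and 244.92 on day 6. Of 21 neuron genes, 4, 2 and 1 had a gene-end peak on days 2, 4 and 6, with Elavl4 present on all 3. The 39 Hox genes, which pattern the body axis, gave 2, 14 and 5 genes (15.8, 14.8 and 9.08 in random lists, percentiles 0, 40.6 and 5.64). Of the 37 without a day 2 peak, 12 had one on day 4 against 3.70 in random lists of such genes (percentile 100). With equal numbers of top-scoring peaks the Hox list gave 1, 7 and 5 members, 6 of them with a day 4 but no day 2 peak. Neighbouring Hox genes share peaks, and the 14 genes of day 4 were marked by 11 distinct peaks. The strongest, of score 1327.55 and rank 11, reached ends of both Hoxa2 and Hoxa3. Of 8 neural crest genes, 2, 1 and 0 had a peak.

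**Figure D2:**
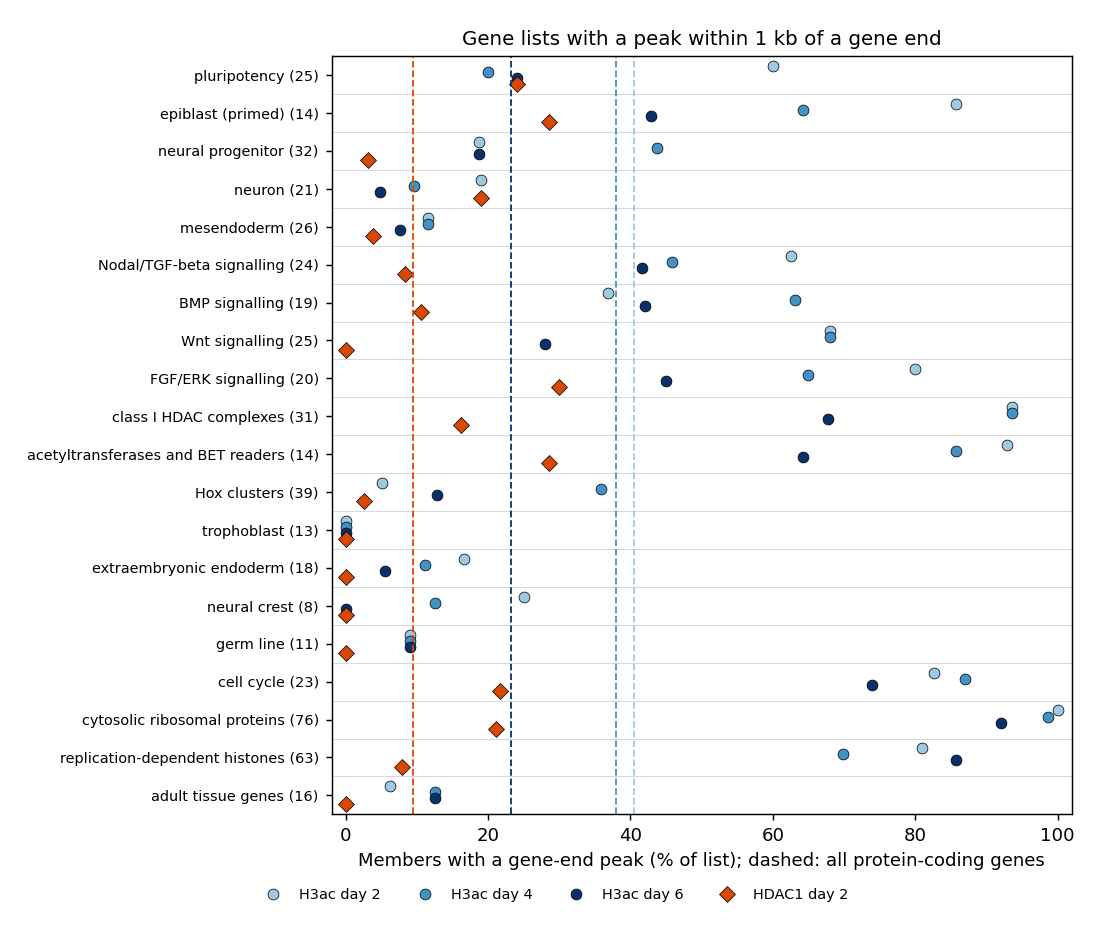
Share of each gene list (%; number of members in parentheses) with a peak within 1 kb of a gene end, for H3ac on days 2, 4 and 6 and HDAC1 on day 2, with dashed lines for all protein-coding genes. The pluripotency list goes from 15 of 25 members on day 2 to 5 on day 4, while the neural progenitor list has 6 of 32 on day 2 and 14 on day 4.

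Mesendoderm genes, which mark the lineage that forms mesoderm and endoderm, were seldom acetylated. Of 26, 3 had a gene-end peak on day 2, 3 on day 4 and 2 on day 6, against 10.5, 9.88 and 6.05 in random lists. T, Eomes, Mixl1, Gsc, Foxa2 and Sox17 had none on any day. Cxcr4 had one on every day, Wnt3 and Evx1 on day 2 but not day 6, Hhex on day 4 alone and Wnt3a on day 6 alone. Trophoblast genes had no gene-end peak on any day (0 of 13), extraembryonic endoderm genes gave 3, 2 and 1 of 18, and germ line genes gave 1, 1 and 1 of 11.

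For the signalling pathways that direct these fates, each list was set against random lists of its own size, and pathways were not tested against each other. Of 24 genes of Nodal and TGF-beta signalling, which drives mesendoderm formation, 15, 11 and 10 had a gene-end peak on days 2, 4 and 6 (9.74, 9.12 and 5.59 in random lists, above their central 95% on days 2 and 6). Foxh1, Skil, Acvr2b and Smad7 had one on every day. Foxh1 was marked at both ends on day 2 and only at its higher-coordinate end on days 4 and 6. Ends of Kifc2 and Ppp1r16a lay within 2 kb of Foxh1 ends, so its peaks may belong to these neighbours. Nodal itself, on chromosome 10 from 61417972 to 61425338, had a peak on day 2 (61418192 to 61418866, score 111.94) and none within 10 kb on days 4 or 6. Gdf3, a related ligand, had one of score 538.31 on day 2 and none later. Tdgf1, the Nodal coreceptor, had one on day 2 (score 226.62) and day 6 (76.16). Lefty1 and Lefty2, which encode Nodal antagonists, had none at their ends, and their nearest day 2 peaks lay 3419 and 5162 bp away. Lefty2 also had a day 4 peak (score 190.03) 5017 bp away. The BMP list gave 7, 12 and 8 of 19 (7.71, 7.22 and 4.42 in random lists, above their central 95% on day 4, though not with a window of 2.5 kb, percentile 96.8). Its 5 genes with a day 4 but no day 2 peak exceeded random lists (percentile 99.8), and they included the BMP targets Id1, Id2, Id3 and Msx1. The Wnt list gave 17, 17 and 7 of 25 (10.1, 9.50 and 5.82, above the central 95% on days 2 and 4). The FGF and ERK list gave 16, 13 and 9 of 20 (8.11, 7.60 and 4.66, above it on each day), with the feedback inhibitors Dusp6, Spry2 and Dusp4 acetylated on every day. Of 31 genes of class I HDAC complexes, 29, 29 and 21 had a peak, and Hdac1, Hdac2, Ncor1, Chd4 and Rbbp4 had one on every day. Acetyltransferases and readers of acetylated histones gave 13, 12 and 9 of 14, cell cycle genes 19, 20 and 17 of 23, and replication-dependent histone genes 51, 44 and 54 of 63.

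These list counts describe single libraries. Of 84 counts (21 lists in 4 libraries), 30 lay above and 21 below the central 95% of random lists, where chance gives 4.2. The tally includes the control lists, whose direction was expected beforehand. Lists share members and libraries share genes, so the counts are not independent. The day 2 count of the pluripotency list (10.1 in random lists, just above the central 95%) lay inside the range of random lists with equal numbers of peaks (percentile 86.7), as did those of Nodal signalling (64.2) and Wnt signalling (75.5), the day 4 counts of Wnt (93.3) and of FGF and ERK signalling (89.2), and the day 6 count of FGF and ERK signalling (96.2). The day 4 count of FGF and ERK signalling also lay inside it with the higher-scoring 50% (80.7) and with 0.5 kb (96.8), and its day 6 count with 2.5 kb (97.4). So did the day 2 count of Wnt signalling with the higher-scoring 50% (72.7) and with 0.5 kb (86.6). The day 4 count of Wnt signalling did so with the higher-scoring 50% (96.8), and the day 6 count of Nodal signalling with 0.5 kb (89.3). With equal numbers, members marked on days 2, 4 and 6 were 6, 9 and 10 for Nodal, 1, 9 and 8 for BMP, 7, 9 and 7 for Wnt, and 10, 7 and 8 for FGF and ERK signalling, so the smaller numbers of Nodal and Wnt genes on day 6 than on day 2 were not seen with lists of equal length. Such lists cannot tell a loss of acetylation from a technical difference between libraries. With equal numbers of top-scoring peaks Nodal, Nanog, Klf4, Fgf5, Otx2 and Nes had no gene-end peak in any list.

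**Figure D3:**
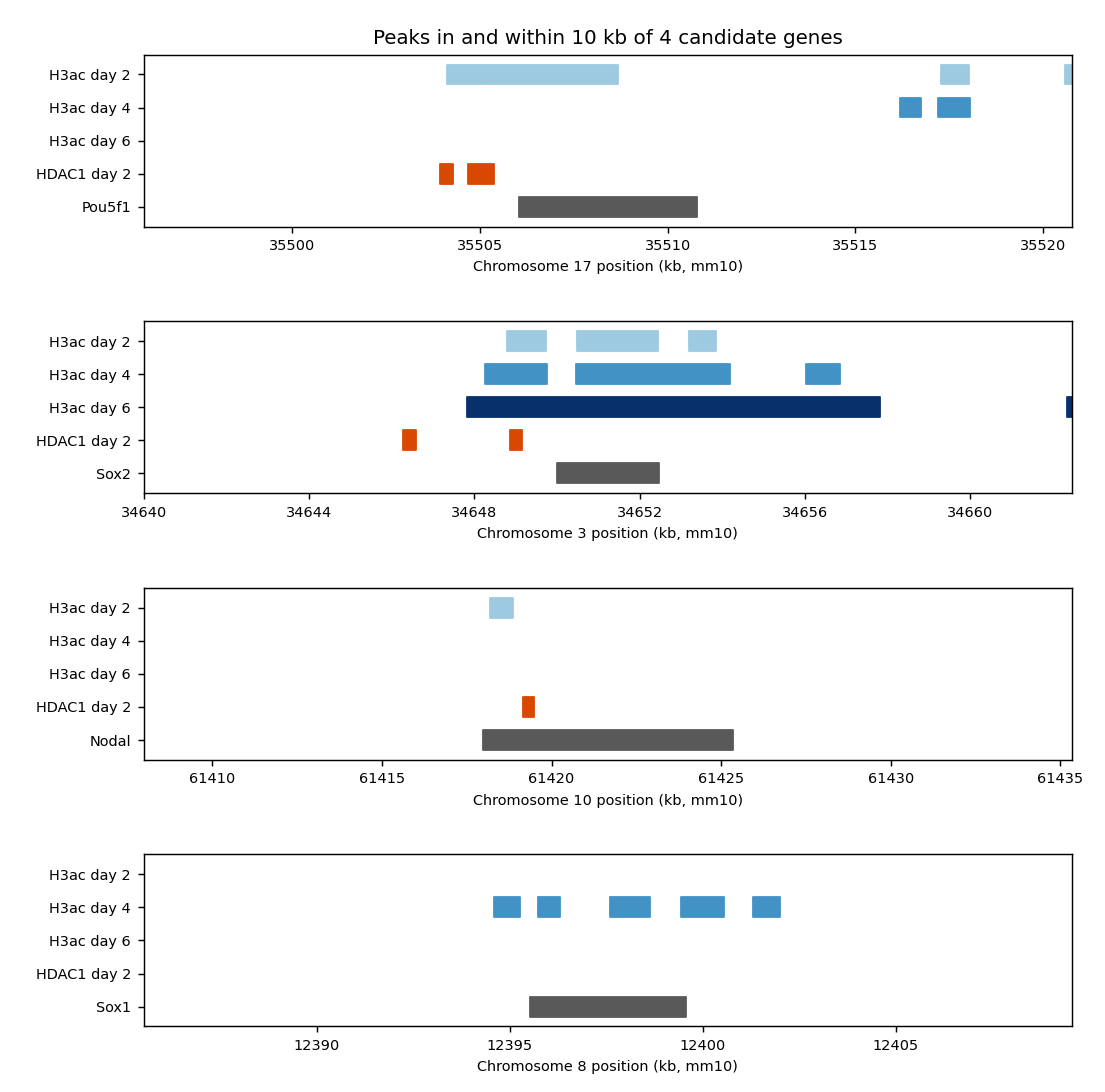
Positions (kb, mm10) of H3ac peaks on days 2, 4 and 6 and of HDAC1 peaks on day 2 in and within 10 kb of Pou5f1, Sox2, Nodal and Sox1, with the gene as a grey bar. Pou5f1 has 4 H3ac peaks on day 2, 2 on day 4 and 0 on day 6, with 2 HDAC1 peaks (the leftmost day 2 bar joins 2 neighbouring peaks), Nodal has 1 H3ac and 1 HDAC1 peak, both of day 2, and Sox1 has 5 H3ac peaks, all of day 4.

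The third comparison set HDAC1 on day 2 beside H3ac of the same day and asked whether the deacetylase sits at acetylated sites. At gene ends the overlap was large. Of the 2057 genes with an HDAC1 gene-end peak, 1661 (80.7%, 79.0 to 82.4%) also had a day 2 H3ac gene-end peak, against 40.6% of all protein-coding genes. Pou5f1, Sox2, Spry2, Mycn, Zic2 and Hdac1 itself were among them. Away from gene ends the overlap was lower: of HDAC1 peaks centred at gene ends 64.1% (61.8 to 66.3%) overlapped a day 2 H3ac peak, of those in gene bodies 14.4% (12.9 to 16.0%), and of those outside protein-coding genes 5.26% (4.29 to 6.42%). Each share exceeded the 0.771% of HDAC1 peaks placed at random along whole chromosomes. No random share was computed by location. Day 2 H3ac peaks were themselves concentrated at gene ends (52.4%), so a lower share elsewhere does not show that HDAC1 avoids H3ac there. The HDAC1 peaks were narrow, with a median width of 311 bp, and 32.7% (31.4 to 34.0%) were centred at gene ends, 35.3% in gene bodies and 32.0% outside protein-coding genes.

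In all, 1464 of 5285 HDAC1 peaks (27.7%, 26.5 to 28.9%) overlapped a day 2 H3ac peak, 25.7% a day 4 peak and 16.5% a day 6 peak. Random placement on the same chromosomes gave 0.771% for day 2, and no placement of 1000 exceeded 1.19%, which made the observed overlap 35.9 times the random one. When placement was restricted to within 10 kb of gene ends, 46.0% of the 3003 HDAC1 peaks there overlapped against 2.93%, or 15.7 times. An H3ac peak of any day overlapped 33.3% (32.0 to 34.6%) of HDAC1 peaks, and 3526 HDAC1 peaks overlapped none. In the other direction, 8.26% (7.86 to 8.68%) of day 2 H3ac peaks overlapped an HDAC1 peak.

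HDAC1 gene-end peaks were more frequent than in random lists in 5 of the 21 gene lists. They marked 16 of 76 ribosomal protein genes (7.14 in random lists, percentile 99.9), 6 of 20 FGF and ERK genes (1.88, percentile 99.6), 6 of 25 pluripotency genes (2.35, percentile 98.2), 4 of 14 epiblast genes (1.32, percentile 98.0) and 4 of 14 acetyltransferase and reader genes (1.32, percentile 97.7). The pluripotency members were led by Pou5f1 (score 145.14), Sox2 (86.55), Gbx2 (61.32) and Klf5 (59.05), the epiblast members were Pou3f1 (117.19), Dnmt3b (81.21), Sox4 and Zic2, and the FGF and ERK members were led by Dusp4, Map2k1, Spry4 and Spry2. With a window of 0.5 kb the epiblast (percentile 81.5), pluripotency (79.2), FGF and ERK (96.3) and acetyltransferase (16.7) counts lay within the range of random lists, and those 4 did so too with the higher-scoring 50% of each list. The random lists were drawn from all protein-coding genes, acetylated or not. HDAC1 gene-end peaks marked 18.7% of genes with day 2 H3ac, against 9.40% of all genes. They marked 21.1% of the 76 ribosomal protein genes, all of which had day 2 H3ac. No list was set against acetylated genes, so an excess beyond acetylation was not shown.

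Other lists carried HDAC1 at their ends in numbers inside the range of random lists. Of mesendoderm genes 1 of 26 did (Mesp1, score 59.05, against 2.44 in random lists, percentile 18.5), of Nodal signalling genes 2 of 24 (Smurf2 and Skil, against 2.26), of BMP genes 2 of 19 (Smad6 and Bmp7, against 1.79), of Wnt genes 0 of 25 (against 2.35), of neural progenitor genes 1 of 32 (Zic5, against 3.01) and of Hox genes 1 of 39 (Hoxc10, against 3.67). Nodal had an HDAC1 peak inside the gene (61419161 to 61419487, score 52.87), 1189 bp from its lower-coordinate end. Fgf5, Otx2 and Esrrb also had internal HDAC1 peaks. T, Eomes, Mixl1, Gsc, Foxa2, Sox17, Lefty1, Lefty2 and Tdgf1 had no HDAC1 peak in or within 10 kb of the gene. Neuron genes gave 4 of 21 (Snap25, Neurod4, Stmn3 and Map2, percentile 91.5), class I HDAC complex genes 5 of 31 (among them Ncor1, Arid4a, Hdac1 and Mbd2), cell cycle genes 5 of 23 and histone genes 5 of 63. Trophoblast, extraembryonic endoderm, neural crest, germ line and adult tissue genes also gave 0. Of 1106 olfactory receptor genes 0 had one, against 104 in random lists, below every list. The highest-scoring HDAC1 gene-end peaks lay at Cacng2 (score 1605.44), Gprin1 (1500.03), Vstm2l (1345.97) and a site shared by Dvl1 and Tas1r3 (1294.90). Cacng2 and Gprin1 encode proteins of neurons, and none of the first 3 had a gene-end H3ac peak on any day.

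The fourth comparison asked whether genes bound by HDAC1 on day 2 differed in later acetylation from other genes acetylated on day 2. Day 4 H3ac was kept more often at bound genes. Of the 1661 genes with both HDAC1 and H3ac gene-end peaks on day 2, 88.3% (86.7 to 89.8%) had a day 4 H3ac gene-end peak, among them Sox2, Spry2, Mycn and Dnmt3b, while Pou5f1, Utf1 and Fgf4 did not. Of the 7217 not bound, 76.8% (75.9 to 77.8%) had one. On day 6 the shares were 53.3% (50.9 to 55.7%) and 49.1% (48.0 to 50.3%).

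Retention went with day 2 score, so bound genes were set against unbound genes of the same decile of day 2 score, with percentiles from matched lists drawn from bound and unbound genes together. That left a difference of 5.17 percentage points on day 4 (matched share 83.1%, percentile 100 among 10000 random lists; 2.70 points with equal numbers of top-scoring peaks, 11.5 without matching) and of -1.97 points on day 6 (matched share 55.3%, percentile 6.32). The day 6 difference lay within the range of random lists, as it did when matched on peak width (-0.387 points, percentile 34.3), with the higher-scoring 50% of each list (-3.41 points, percentile 2.89) and with a window of 0.5 kb (-2.64 points), and without matching it turned to 4.17 points (percentile 99.9). It lay outside that range with equal numbers of top-scoring peaks (-3.18 points, percentile 1.66), with a window of 2.5 kb (-2.31 points, percentile 2.39) and at gene ends with no other gene end within 2 kb (-4.32 points, percentile 0.85). Among genes with no day 2 H3ac gene-end peak, 114 of 396 HDAC1-bound genes (28.8%, 24.5 to 33.4%) and 1186 of 12613 unbound genes (9.40%, 8.91 to 9.92%) had one on day 4, and 12.1% (9.27 to 15.7%) and 4.91% (4.54 to 5.30%) on day 6. Fzd3 (HDAC1 score 57.04), Bmp7 (50.18) and Klf5 were bound genes of this kind. These shares were not matched, since genes without a day 2 peak have no day 2 score. The unbound genes included 1103 olfactory receptor genes, none of which had a later peak. The difference therefore cannot be tied to HDAC1.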

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

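The tests of regions that respond to any antibody, of list length on chromosome X and of REST targets outside the 21 gene lists were chosen only after the result was seen. The day 2 H3ac list held 10 peaks on unplaced contigs, a signal in sequence that the comparisons did not use, and the strongest of these had score 1284.31 and rank 12 in that list.

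Pluripotency genes with a day 2 H3ac gene-end peak often had none later. A higher effective threshold in a later library that acts on all genes alike would leave them at the rate of genes of the same day 2 score. On day 4 they lay below every matched list (5 of 15 kept against 11.6, percentile 0), which argues against such a threshold as the whole cause. On day 6 they lay inside the range (5 of 15 against 7.69, percentile 7.11), so a uniform threshold may account for the day 6 counts. A difference between the days of differentiation remains open as a biological explanation for day 4, and day and library are the same thing in this design.

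Some of the highest-scoring 10% of HDAC1 peaks lay in genes of neurons, such as Cacng2 and Snap25, and an H3ac peak of any day overlapped 25.6% of these 528 peaks (22.0 to 29.5%), against 34.2% (32.8 to 35.5%) of the rest. These peaks drew attention because they lay outside H3ac peaks, so this share says nothing further about regions that give strong signal with any antibody, and that explanation stays open. A candidate explanation is HDAC1 at sites of REST, a repressor of neuronal genes that recruits HDAC1 complexes. Of 31 genes listed as REST targets from general knowledge and not looked at singly before, 8 had 1 or more of these HDAC1 peaks in or within 10 kb of the gene, against 0.849 in lists matched on gene length (percentile 100), and without members of the 21 gene lists, such as Stmn3, it was 7 of 26 against 0.729 (percentile 100). Sequence motifs were not analysed here, so REST itself was not measured and the explanation stays a hypothesis.

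Chromosome X held 3.60% of day 6 H3ac peaks (3.14 to 4.12%), against 1.61% on day 2 (1.43 to 1.80%) and 194 of 12945 on day 4 (1.30 to 1.72%). It holds 4.41% of protein-coding genes. In the full lists X peaks numbered 279 on day 2 and 200 on day 6, so the share rose without more X peaks. With equal numbers of top-scoring peaks they numbered 76 and 193. List length and joining of neighbouring peaks would remove the difference, but the day 6 share was 3.65% with equal numbers of top-scoring peaks (1.44% on day 2) and 3.47% after merging peaks within 1 kb (1.68% on day 2). A higher threshold on day 6 that acts on all genes alike is argued against too, since 101 of 179 X-linked genes kept their day 2 peak on day 6 (56.4%, percentile 100), where genes elsewhere of the same day 2 score kept 42.6%. On day 4 the same genes kept fewer than others did (59.8% against 71.8%). Differences between the cultures or inputs behind the libraries, such as in X copy number, may also give this pattern, were not tested, and no biological explanation was tested.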

How the results depend on the processing

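The gene ends with no other end within 2 kb, and peaks anywhere in a gene or within 10 kb, were tried after the data were examined, and all other alternatives were planned. No paired analysis was possible because each target and day had 1 library. Alternatives that needed transcript starts (TSS definition) or CpG observed/expected ratios as background were not run, since strand, transcripts and sequence were not used here. Autosomes alone and autosomal genes changed the main values little. With autosomal genes, the difference at HDAC1-bound genes stayed outside the range of random lists on day 4 and inside it on day 6. Among the main values, merging was run only for the day 6 to day 2 ratios. These were 0.372 against 0.320 for peak number and 0.842 against 0.904 for covered length. The cause of a shift was not tested unless stated.

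With equal numbers of top-scoring peaks, 64.2% and 57.3% of day 2 H3ac peaks overlapped day 4 and day 6 peaks and 50.7% of day 6 peaks overlapped day 2 peaks. Gene-end peaks marked 4873 genes on day 2 and 4982 on day 4, of day 2 genes 72.8% were kept on day 4 and 60.2% on day 6, and 74.5% (day 2) and 72.3% (day 4) of midpoints lay at gene ends. Of HDAC1 peaks 17.7% overlapped day 2 H3ac and of HDAC1-bound genes 54.3% had it. HDAC1-bound genes differed from matched ones by 2.70 points on day 4 and by -3.18 points on day 6, outside the range of random lists.

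With the higher-scoring 50% of each list, 57.5% and 30.3% of day 2 peaks overlapped day 4 and day 6 peaks and 74.9% of day 6 peaks overlapped day 2 peaks. Day 2 genes kept were 71.5% on day 4 and 33.8% on day 6, 2822 genes were marked on day 6, midpoints at gene ends were 69.0% on day 2 and 72.2% on day 4, 23.4% of HDAC1 peaks overlapped day 2 H3ac and 70.3% of HDAC1-bound genes had it.

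With gene ends that have no other gene end within 2 kb, 5905, 5484 and 3353 genes were marked on days 2, 4 and 6, 74.6% and 47.2% of day 2 genes were kept on days 4 and 6, 73.3% of HDAC1-bound genes had day 2 H3ac, and the day 6 difference was -4.32 points. Fewer gene ends enter by construction.

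With a window of 0.5 kb, midpoints at gene ends were 30.5%, 32.0% and 37.4% for H3ac on days 2, 4 and 6 and 23.6% for HDAC1. Day 4 kept 77.3% of day 2 genes, and 78.6% of HDAC1-bound genes had day 2 H3ac. With 2.5 kb, midpoints at gene ends were 66.1%, 74.7%, 83.5% and 41.3%, and the day 6 difference was -2.31 points. A wider window takes in more midpoints by construction.

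Overlap by 50% of the shorter peak gave 47.1% and 34.3% for day 2 peaks on days 4 and 6 and 23.3% for HDAC1. Overlap within 1 kb gave 59.3%, 38.3% and 34.9%, 83.8% for day 6 peaks on day 2, and an HDAC1 overlap 18.0 times the random one. Placement within 10 kb of gene ends gave 15.7 times. Matching on peak width gave 6.24 points for HDAC1-bound genes on day 4 and -0.387 on day 6, and no matching gave 11.5 and 4.17 points, which turned the day 6 direction.

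Of 84 gene list values, 16 crossed into or out of the range of random lists with the higher-scoring 50%, 13 with equal numbers, 7 with 2.5 kb and 11 with 0.5 kb, and 7 of 21 HDAC1 values did so within 10 kb of the gene. None changed sides. Of 24 candidate genes, the days or targets with a peak differed for 11 within 10 kb, 8 with equal numbers, 6 with the higher-scoring 50%, 5 with 0.5 kb, 6 with 2.5 kb and 0 with autosomal genes.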

Other observations

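All values in this part were chosen after the data were examined, except the counts of histone and ribosomal protein genes within 1 kb of gene ends.

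Several high-scoring HDAC1 peaks lay in genes of neurons, some of which were picked for their peaks. Npas4, an activity-dependent transcription factor of neurons, held the HDAC1 peak ranked 7 of 5286 (chromosome 19, 4988911 to 4989423, score 2882.57), and L1cam, a neural adhesion molecule on chromosome X, held the peak ranked 33 (73869350 to 73869670, score 1256.71). Glra1 (score 1211.63), Celsr3 (924.13), Vgf (575.27), Snap25 (434.46), Chgb (325.18), Sst (291.40) and Chga (143.56) also had HDAC1 peaks among the highest-scoring 10%, inside the gene. The peaks at Npas4, L1cam, Celsr3, Snap25, Chga, Chgb and Sst overlapped no H3ac peak of the 3 days. The Vgf and Unc13a peaks overlapped day 2 H3ac peaks, and the Glra1 peak overlapped peaks of days 4 and 6. HDAC1 peaks outside the highest-scoring 10% also lay at REST targets more often than at matched genes (14 of 31 genes against 6.87, percentile 99.8). In the same window of the gene and 10 kb around it, 11 of the 21 neuron genes had an HDAC1 peak (5.46 in lists matched on gene length, percentile 99.5), as did 12 of 20 FGF and ERK genes (4.36, percentile 100), 10 of 14 epiblast genes (3.24, percentile 100), 11 of 25 pluripotency genes (4.93, percentile 99.8), 14 of 31 class I HDAC complex genes (7.74, percentile 99.3), 24 of 76 ribosomal protein genes (12.1, percentile 100) and 9 of 63 histone genes (3.59, percentile 99.5), so the excess was not particular to neuron genes. The numbers were 4 of 32 neural progenitor genes (6.32, percentile 15.9) and 3 of 26 mesendoderm genes (4.91, percentile 17.6). These lists were matched on gene length and not on H3ac.

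Replication-dependent histone genes, which lie in dense clusters, included more members with a gene-end H3ac peak on day 6 (54 of 63) than on day 4 (44). Of the 51 with a day 2 peak, 50 had one on day 6, against 24.1 in matched lists (percentile 100), and 41 on day 4 against 40.1 (percentile 62.7). H3c8 had a peak of score 315.28 on day 2 and of 1203.02 on day 6, though scores of different lists cannot be compared. Neighbouring histone genes share peaks: the 51 genes of day 2 were marked by 35 distinct peaks, the 44 of day 4 by 28 and the 54 of day 6 by 36. Ribosomal protein genes, also short, kept 70 of 76 on day 6 against 56.9 (percentile 100).

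On chromosome X, 63 genes had a gene-end H3ac peak on day 6 and none on day 2, of 667 such genes in all, and 39 of them had none on day 4 either. Losses outnumbered these gains: 179, 145 and 164 of 966 X-linked genes had such a peak on days 2, 4 and 6. On other chromosomes the numbers were 8699, 8168 and 4932. The highest-scoring of those 63 were Efnb1, Fmr1 and Brcc3. HDAC1 had 24 peaks on chromosome X (0.454%, 0.305 to 0.675%), and 1 of 966 X-linked genes had an HDAC1 gene-end peak.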
